A study of Mus musculus with 12 samples.

How the data were processed

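Total RNA of the terminal ileum of 12 female mice was measured on a NanoString nCounter panel. The mice formed 4 groups of 3 by genotype label (IL10 or C57) and by the inoculum of the mothers, either control cecal contents or the antibiotic-perturbed contents that the labels call STAT. RNA was extracted with TRIzol and RNeasy columns and hybridised to reporter and capture probes, per the labels' protocols. The groups are called WT_control and WT_STAT for the C57 label, and IL10_control and IL10_STAT for the IL10 label. They were taken from the genotype and treatment labels of each sample, and the replicate numbers used here follow the order of the sample records. The labels gave no litters, mothers or cages, so every p-value measured the spread between these samples. The inoculum was that of the mothers, and mice of the same group may share a mother, litter or cage. Each n therefore counts mice, and the p-values may not cover the spread between mothers. Differences between mothers, litters or cages could not be separated from inoculum or genotype label in any contrast. The samples were called IL10-labelled and C57-labelled, because the Il10 signal ran against the genotype label in every sample.

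The deposited table held 547 genes as a normalized linear signal for each sample, with 0 columns that belonged to no sample. Its unit was read from the values, since the normalization and the software were not given in the sources used here. In each sample, 100% of the positive values lay a whole number of steps of 1 size above the lowest positive value, within 0.01 counts. Barcode counts minus a background, set to 0 where negative and multiplied by a per-sample factor, would give this. What that factor was fitted to was not given in the sources used here. No control probes were in the table. Of the symbols, 531 were current mouse gene symbols, 14 were synonyms and 2 were unmatched.

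From the step size, the counts above background were 146691 to 365850 in the WT_control samples, 191012 to 276579 in WT_STAT, 398625 to 506141 in IL10_control and 541733 to 717454 in IL10_STAT. The most abundant gene held 9.03% to 14.3% of the signal of a sample. Between 93 and 107 genes were under a signal of 20 in the IL10-labelled samples, and between 140 and 185 in the C57-labelled samples. The lowest ratio of the variance between replicates to the counting variance was 7.25, as an average over genes. Each mouse was measured 1 time, so the spread beyond counting could not be divided between mice, RNA, hybridisation and scaling.

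Genes with a signal of at least 20 in at least 3 of the 12 samples were tested, which kept 457 and left out 90. Values were analysed as log2(signal + 1) with limma 3.58.1 in R 4.3.3, in 1 linear fit with a coefficient for each of the 4 groups and moderated variances (lmFit and eBayes). The 5 contrasts were STAT against control within each genotype label, the difference between those 2 effects (the interaction), and IL10-labelled against C57-labelled samples under each inoculum. P-values were adjusted by the Benjamini-Hochberg method over the 457 genes, and a gene passed at an adjusted p under 0.05. Log2 differences are given with their standard errors from the fit. For a gene under 20 in all samples of 1 group, the fold was given as a lower bound, with that group set to 20. The exact permutation p of 3 against 3 samples cannot be below 0.1, so no such test was used for single genes.

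Gene lists were IL-10 signalling, Th1 and interferon-gamma, type I interferon, Th17 and IL-22, antimicrobial and acute-phase, inflammatory cytokines and chemokines, inflammasome and IL-1 family, TLR, NOD and NF-kB, MHC class II, MHC class I and immunoproteasome, Th2 and type 2, regulatory T cell, complement, and autophagy. Lists of marker genes covered T cell, cytotoxic and NK cell, B cell, plasma cell, macrophage and monocyte, dendritic cell, neutrophil, mast cell and eosinophil, epithelium, endothelium and stroma, organised lymphoid tissue (Peyer patch) and a housekeeping reference. Of these 26 lists, 23 had at least 4 tested members and were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of each contrast. Camera asks whether a list moved against the other genes of the panel. Genes passing after adjustment over the members of 1 list alone were also counted.

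The groups, contrasts, tests, filter, gene lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule named Il10 first, then the 12 largest increases and the 12 largest decreases among passing genes whose groups did not overlap, with no overlap rule for the interaction. Where fewer than 12 genes passed, it named the 12 genes with the smallest p. It also named up to 4 members of each described list, and always Il10, Ifng, Tnf, Il1b, Il6, Il17a, Il22, Nos2 and Foxp3. Some genes that this rule names are not reported here. Alternatives fixed at the same time were centring each sample on its median, quantile normalization, no filter, a filter of 40 in 6 samples, a pseudocount of 10, only the 2 groups compared, trended and robust variances, array weights (statmod 1.5.0), leaving out each sample in turn, an estimated correlation in camera, and fry. Added after the data were seen were scaling on 17 broadly expressed genes, setting values under 20 to 20, leaving out the 2 samples of lowest depth, and the mean of the B cell list as a covariate.

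The code was tested on simulated data for 457 genes, with 200 changed genes and 20 simulations for each contrast. It recovered 63.7% of 2-fold and 93.6% of 4-fold changes for STAT in the IL10 label, 63.1% and 91.8% for STAT in the C57 label, and 33% and 83% for the interaction. For the genotype contrasts it recovered 63.8% and 92.5% under control, and 64.8% and 93.4% under STAT. Between 2.76% and 3.04% of calls were false, and a list shifted by 1 on the log2 scale was recovered in 20 of 20 simulations of each contrast. Over these simulations camera also called unshifted lists, 2 for STAT in the IL10 label and 0 for each other contrast. Genes were drawn independently of each other, with the same spread in all samples, no floor and no difference in depth. With 200 changed genes the adjusted threshold is also easier to reach than where few genes change. The recovered shares therefore do not give the power of the STAT comparisons in the real data. Because the simulated genes were independent, the false calls and the unshifted lists called do not give those of the real data either. There, regrouped samples gave as many as 7 lists in the interaction.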

Results

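The 12 samples separated first by genotype label. With each sample centred on its median, the first principal component of the log2 signal held 77.7% of the variance and the second 5.15%. On the first component the IL10-labelled samples lay between -22.9 and -8.36, and the C57-labelled samples between 15.3 and 20.9. The sample nearest to the other genotype was IL10_control 3, at -8.36. Correlations between replicates of a group ran from 0.872, for IL10_control 2 and 3, to 0.987. The IL10-labelled samples also had more counts above background (398625 to 717454) than the C57-labelled samples (146691 to 365850). The ranges did not overlap, so genotype label and these counts could not be separated. Higher counts may come from technical depth or from higher signal of the panel genes, and this was not tested.

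Il10, the gene named in the genotype label, ran against that label in all 12 samples. Its signal was 0.452, 1.02 and 0 in the 3 WT_control samples and 0 in each WT_STAT sample. In the IL10_control samples it was 35.2, 74.4 and 24.9 (mean 44.8 ± 26.1 SD), and in the IL10_STAT samples 31.6, 49.2 and 38.6 (39.8 ± 8.86 SD). The part of the Il10 transcript that the probe binds was not given in the sources used here. A probe outside the disrupted part of the gene would check nothing, because a transcript of the disrupted allele could still bind it. Directions between genotypes are therefore given between IL10-labelled and C57-labelled samples, as labelled.

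**Figure D1:**
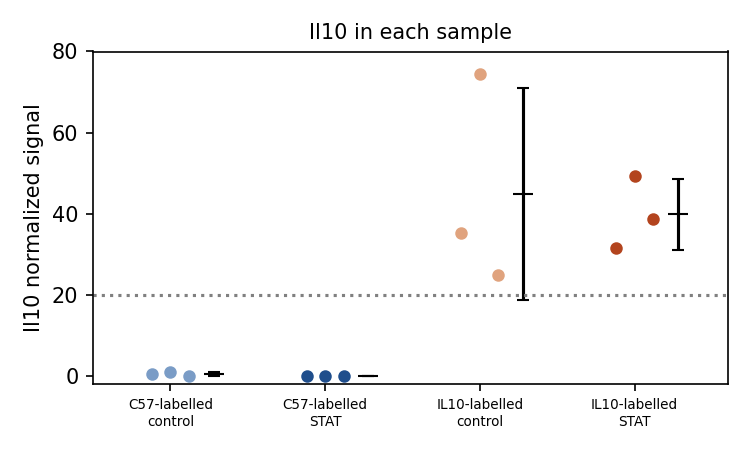
Il10 signal in each of the 12 samples by group, with mean ± SD beside the points. The dotted line marks the signal of 20 used as the detection floor.

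STAT against control in IL10-labelled samples addressed the question of the study, and no gene passed. The largest differences by p were decreases that did not pass: Cd163, the haemoglobin scavenger receptor of resident macrophages, had a signal of 74.5 ± 31.4 SD in IL10_control and 16.0 ± 9.41 SD in IL10_STAT. Its log2 difference was -2.23 ± 0.45 (4.70-fold lower with STAT, n = 3 and 3, adjusted p = 0.102 in limma's test). Il18, an epithelial cytokine of the IL-1 family, differed by -1.11 ± 0.22 (2.16-fold lower, adjusted p = 0.102). For both genes all 3 STAT samples lay below all 3 control samples. The cytokines Tnf (0.53 ± 0.57), Il1b (1.02 ± 0.87), Il6 (1.01 ± 1.10) and Il17a (0.69 ± 0.66) were not separated from 0.

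The 10 other genes of smallest p also did not pass. Cd36, a lipid scavenger receptor, differed by -1.39 ± 0.35, and Lcp2, a T cell receptor adaptor, by -0.92 ± 0.23 (adjusted p = 0.277 for both). Cxcl12, a stromal chemokine (-0.77 ± 0.23), Mr1, which presents vitamin B metabolites (-0.86 ± 0.25), and Maf, a transcription factor (-1.56 ± 0.47), had adjusted p = 0.437. Cd109, a TGF-beta co-receptor (-1.28 ± 0.39), had 0.444, and the peptidase Dpp4 (-1.31 ± 0.43) and complement factor D, Cfd (-2.70 ± 0.89), had 0.542. Il6ra, the IL-6 receptor, differed by -0.79 ± 0.27 (0.604), and the IL-1 antagonist Il1rn by 0.93 ± 0.33 (0.625). All of these decreases kept their sign when each sample was centred on its median. Il10 (-0.04 ± 0.38) turned to 0.24 under median centring, and Nos2, the inducible nitric oxide synthase (0.06 ± 0.34), and Foxp3, the regulatory T cell factor (-0.38 ± 0.95), were not separated from 0.

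By list, inflammatory cytokines and chemokines had a median of 0.50 (0.45 with values under 20 set to 20) against a panel median of -0.21, with camera adjusted p = 0.000124 and adjusted p = 0.855 with an estimated correlation. No member passed over all genes or over the list alone. Its members of smallest p were Lif, a cytokine of the IL-6 family (0.66 ± 0.29, adjusted p = 0.718), Ccl5, a T cell chemokine (-0.61 ± 0.31), and Cxcl3, a neutrophil chemokine (1.49 ± 1.15). The T cell list had a median of -0.53 (camera adjusted p = 0.0109, and 0.855 with an estimated correlation), with Cd247, a T cell receptor chain (-0.56 ± 0.25), Tcf7, a T cell transcription factor (-0.79 ± 0.35), and Cd3d (-0.44 ± 0.20), all at 0.718. The type I interferon list (median 0.01) and the MHC class I and immunoproteasome list (0.04) each had camera adjusted p = 0.0165 and 0.855 with an estimated correlation. Their members Irf7, a regulator of interferon genes (0.46 ± 0.18), Ifit2, an interferon-induced gene (0.49 ± 0.34), and H2-Q10, an MHC class I gene (0.38 ± 0.20), did not pass. Camera placed these last 2 lists as higher, with medians near 0, because the panel median lay below 0.

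No list of this comparison passed with an estimated correlation. At the preset correlation the camera results depended on single samples and, for 2 lists, on other settings. Without IL10_control 3 the inflammatory list had 0.115, over a range of 1.61e-05 to 0.115 in the alternatives with the preset correlation. The T cell list had 0.0573 without IL10_STAT 1 and 0.118 without IL10_control 2, and 0.127 with array weights (range 0.000114 to 0.127). The type I interferon list had 0.0707 without IL10_control 1 and 0.0804 without IL10_control 2 (0.00421 to 0.0804). The MHC class I list had 0.118 without IL10_STAT 3, 0.0511 without IL10_control 1 and 0.288 without IL10_control 2, and with all samples 0.118 under quantile normalization and 0.124 with no filter (0.000917 to 0.288). Over its own list alone, Il18 passed in the Th1 and inflammasome lists and Cd163 in the macrophage list. In limma's test 0 of 457 genes passed, against 31 at an unadjusted p under 0.05 (3 higher and 28 lower). The groups did not overlap for 106 genes (23.2%). Chance gives 10% on average, but genes measured in the same samples can move together. Whether 23.2% lies beyond chance was therefore not tested. Fry called no list (lowest adjusted p = 0.758).

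STAT against control in C57-labelled samples gave 4 genes that rose and 0 that fell. Irf4, a transcription factor of activated B cells and plasma cells, rose from 23.9 ± 1.20 SD to 81.6 ± 14 SD (log2 1.72 ± 0.25, 3.29-fold, n = 3 and 3, adjusted p = 0.0121 in limma's test). Slamf7, a receptor of plasma cells and activated leukocytes, rose from 131 ± 22.1 to 283 ± 35.9 (1.11 ± 0.20, 2.17-fold). Cxcl9, an interferon-gamma-induced chemokine, rose from 26.3 ± 9.37 to 68.8 ± 15.3 (1.38 ± 0.26, 2.61-fold). Ccl8, a monocyte chemokine, rose from 124 ± 61.5 to 424 ± 149 (1.83 ± 0.35, 3.55-fold). The last 3 had adjusted p = 0.0315, and all 4 were higher in every STAT sample than in any control sample.

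**Figure D2:**
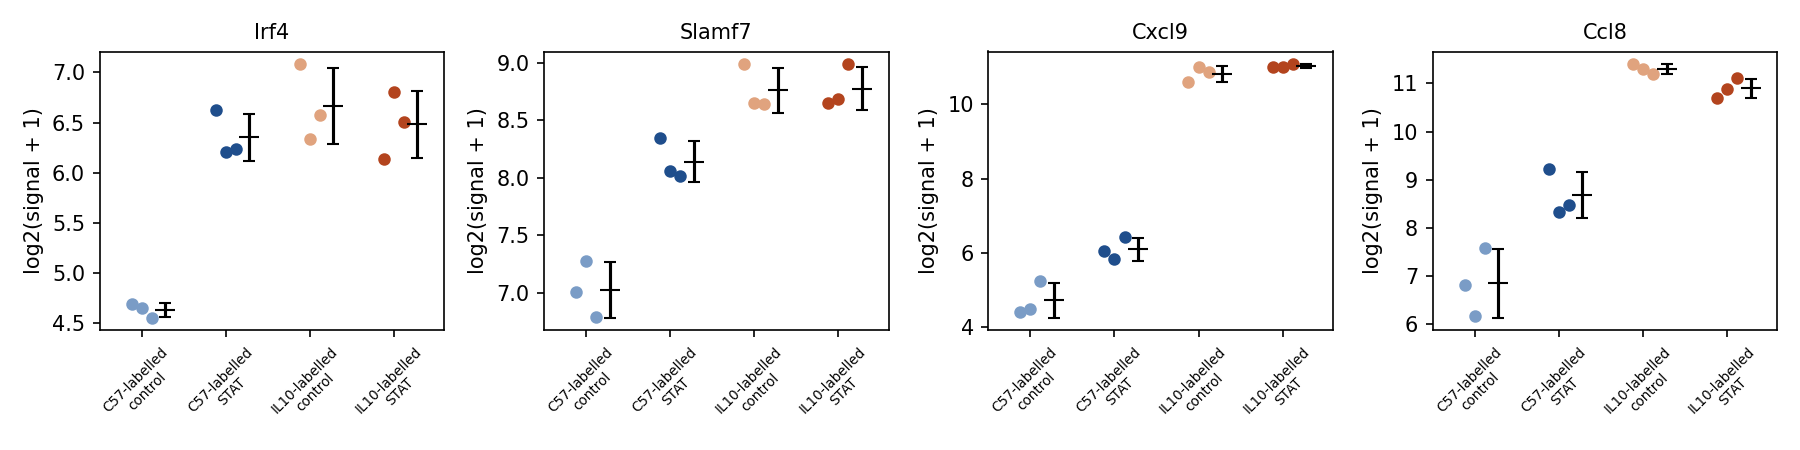
Log2 signal of Irf4, Slamf7, Cxcl9 and Ccl8 in each sample by group, with mean ± SD beside the points. In C57-labelled samples these 4 genes rose with STAT, and none passed when each sample was centred on its median or quantile normalized.

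The 4 calls depended on the scaling and on single samples. The panel median was 0.24, and 0 genes passed after median centring or quantile normalization, where the 4 genes stayed higher: Irf4 by 1.35 and 1.01, Slamf7 by 0.74 and 0.72, Cxcl9 by 1.01 and 0.73, and Ccl8 by 1.46 and 1.36. Scaled on the broadly expressed genes 4 passed, of which only 2 were among these 4 genes. There Cxcl9 had adjusted p = 0.0888 and Ccl8 0.0739 in limma's test. Across all alternatives the adjusted p ran from 0.00355 to 0.214 for Irf4, 0.00399 to 0.31 for Slamf7, 0.00111 to 0.509 for Cxcl9 and 0.00355 to 0.31 for Ccl8. The number of passing genes was 0 without WT_control 1 or without WT_STAT 1, and 44 without WT_STAT 3, all 4 genes among them. Without WT_STAT 2 it was 2, 1 higher and 1 lower, and of the 4 genes only Irf4 passed. Without WT_control 2 it was 4, and of the 4 genes only Irf4 and Slamf7 passed. Without WT_control 3 it was 3, and Slamf7 was lost. At an unadjusted p under 0.05 there were 79 genes, 77 higher and 2 lower. The groups did not overlap for 73 genes (16%, where chance gives 10% on average), and whether this lies beyond chance was not tested.

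The next genes did not pass. Batf3, a dendritic cell transcription factor, was at least 1.45-fold higher (log2 1.06 ± 0.22, adjusted p = 0.0502), and Tmem173, the STING adaptor, differed by 1.04 ± 0.24 (0.0839). At adjusted p = 0.0896 were the monocyte chemokine Ccl12 (1.30 ± 0.31), the activation marker Cd69 (1.88 ± 0.47), the macrophage marker Emr1 (0.81 ± 0.20) and the MHC class II genes Cd74 (0.92 ± 0.23), H2-Ab1 (0.85 ± 0.21) and H2-Aa (0.85 ± 0.21). Il10 (-0.52 ± 0.38), Tnf (0.66 ± 0.57), Il1b (0.68 ± 0.87), Il17a (-1.28 ± 0.66) and Nos2 (-0.43 ± 0.34) did not pass either. Nor did Il6 (0.12 ± 1.10, and -0.25 when centred) and Foxp3 (0.28 ± 0.95, and -0.09 when centred).

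By list, MHC class II had the lowest camera p at the preset correlation, with a median of 0.90 and a mean of 1.03 (camera adjusted p = 8.19e-05, and adjusted p = 0.842 with an estimated correlation). Over all genes 0 of its 8 members passed, and 8 of 8 passed when adjusted over the list alone. The median stayed above 0 under every scaling, at 0.53 when centred, and camera kept the list without any single sample (alternatives with the preset correlation 1.99e-07 to 0.00658). The plasma cell list had a median of 1.10 (0.87 floored), with 1 of 4 members risen (Irf4) and 2 over the list alone. Its camera adjusted p was 0.0436, and adjusted p = 0.842 with an estimated correlation. The macrophage and monocyte list had a median of 0.60 (0.60 floored), 0 of 13 members over all genes and 4 over the list alone (0.0436, and adjusted p = 0.976 with an estimated correlation).

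The plasma cell list lost its camera call without WT_control 1 (0.134), WT_control 2 (0.116) or WT_STAT 3 (0.218). With all samples it was lost when centred (0.0907), quantile normalized (0.147) or scaled on the broadly expressed genes (0.0971), with only the 2 groups (0.0544) and with array weights (0.12), and it was lost without the 2 samples of lowest depth (0.205), over a range of 0.00837 to 0.218. The macrophage list lost it without WT_control 1 (0.126), WT_control 2 (0.225) or WT_STAT 1 (0.072). With all samples it was lost when centred (0.0606), quantile normalized (0.0802) or scaled on the broadly expressed genes (0.0971), with the filter at 40 (0.061), with only the 2 groups (0.0544) and with the B cell covariate (0.0952), over 0.0124 to 0.225. The B cell and Peyer patch lists did not pass. The B cell list had a median of 1.34 (0.57 floored, camera adjusted p = 0.227) with 0 of 12 members passing, and the Peyer patch list 0.93 (0.50 floored, 0.255) with 0 of 13, and both had 0 over the list alone and adjusted p = 0.976 with an estimated correlation. The B cell surface gene Ms4a1 differed by 1.34 ± 0.90 and did not pass. Ms4a1 was 41.2, 118 and 79.3 in the control samples and 349, 298 and 61.6 in the STAT samples, so WT_STAT 3 lay within the control range. When centred, camera called the B cell list higher (0.0298) and the TLR, NOD and NF-kB list lower (0.0137). With an estimated correlation and the deposited scaling each had adjusted p = 0.976, and 0 lists passed. Fry gave plasma cell 0.00738 and MHC class II 0.0394.

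The difference between the 2 STAT effects was tested by itself, and no gene passed. The smallest p-values belonged to Irf4 (-1.90 ± 0.35) and Batf3 (-1.59 ± 0.31), both at adjusted p = 0.0815 in limma's test, n = 3 in each of 4 groups. Irf4 stood at 103 ± 28.3 SD in IL10_control and 90.1 ± 20.8 in IL10_STAT, against the rise in the C57-labelled samples. At adjusted p = 0.104 followed Ccl8 (-2.23 ± 0.49), Mr1 (-1.43 ± 0.36), Cd163 (-2.52 ± 0.63, with an IL10_STAT mean under 20), Il18 (-1.25 ± 0.32), the monocyte receptor Cx3cr1 (-1.26 ± 0.33) and Slamf7 (-1.10 ± 0.29). With them were Cxcl12 (-1.21 ± 0.32), the IL-7 receptor Il7r (-1.55 ± 0.41), the T cell adhesion gene Cd2 (-1.84 ± 0.49) and the kinase Map4k1 (-1.41 ± 0.38). These 12 genes stayed below 0 when each sample was centred, as did Cxcl9 (-1.17 ± 0.36).

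**Figure D3:**
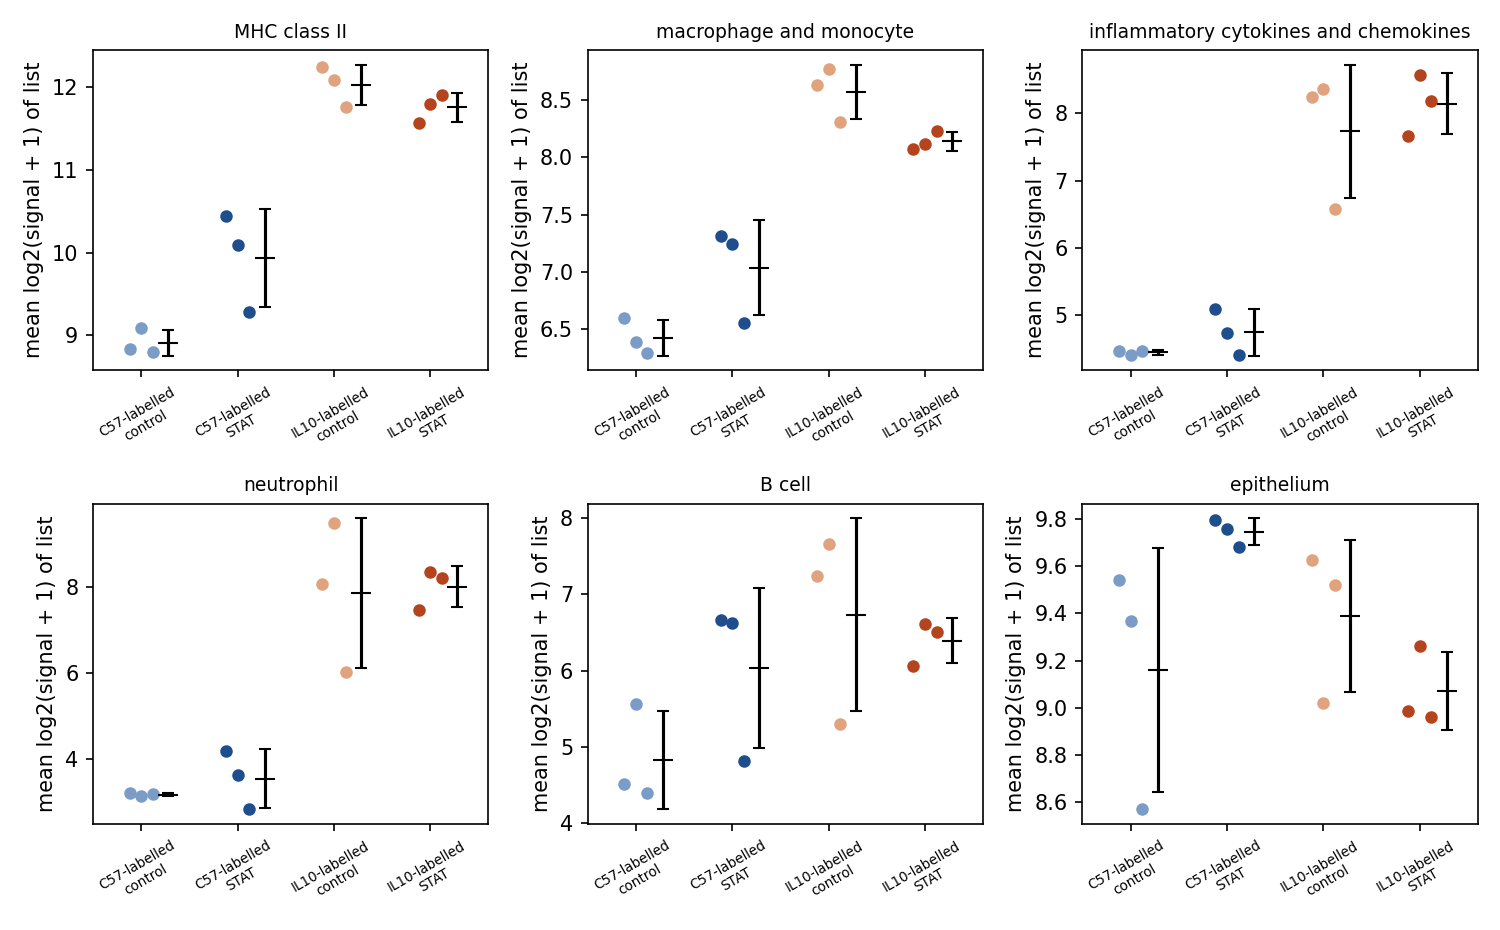
Mean log2 signal of gene lists in each sample by group. The MHC class II list was higher in WT_STAT than in WT_control, and in the IL10-labelled samples it was not.

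The panel median of the interaction was -0.48 and turned to 0.17 when each sample was centred. MHC class II had a median of -1.20 and a mean of -1.30 (camera adjusted p = 0.00301, and adjusted p = 0.743 with an estimated correlation). Over all genes 0 of its 8 members passed and 7 over the list alone. Its camera call held without any single sample, over a range of 0.000117 to 0.0314 in the alternatives with the preset correlation, and its median stayed below 0 under every scaling. The mean of the list per group was 8.91 ± 0.15 SD in WT_control, 9.94 ± 0.59 in WT_STAT, 12.03 ± 0.25 in IL10_control and 11.76 ± 0.18 in IL10_STAT. Macrophage and monocyte genes had a median of -0.99 (0.0373, and adjusted p = 0.743 with an estimated correlation), with 5 over the list alone. That call was lost without IL10_STAT 2 (0.053), IL10_control 2 (0.0887), WT_control 1 (0.061) or WT_control 2 (0.174). With all samples it was lost when centred (0.0679), quantile normalized (0.06) or scaled on the broadly expressed genes (0.0631), with no filter (0.0584), the filter at 40 (0.0605) and array weights (0.0601), over 0.013 to 0.174.

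The inflammatory list had a median of 0.24 and a mean of 0.11, and camera placed it as higher (0.0188, and adjusted p = 0.743 with an estimated correlation), while fry gave the direction lower (0.895). Its call was lost without IL10_STAT 2 (0.053), IL10_control 3 (0.272), WT_control 3 (0.365) or WT_STAT 2 (0.0743), or without the 2 samples of lowest depth (0.141). With all samples it was lost when centred (0.22) or quantile normalized (0.0688), with no filter (0.177), the filter at 40 (0.224) and array weights (0.0684), over 0.000814 to 0.365. When centred, camera called the TLR, NOD and NF-kB list higher (0.00205), and with an estimated correlation and the deposited scaling it had adjusted p = 0.743, where 0 lists passed. Il1b (0.34 ± 1.24), Il6 (0.89 ± 1.55), Il17a (1.97 ± 0.94), Nos2 (0.49 ± 0.47), Il10 (0.48 ± 0.53) and Foxp3 (-0.66 ± 1.34) did not pass, nor did Tnf (-0.13 ± 0.80, and 0.52 when centred). In limma's test 0 of 457 genes passed, against 97 at an unadjusted p under 0.05 (1 higher and 96 lower). Without WT_STAT 3 there were 58, and 1 without WT_control 3 or WT_STAT 2. Across genes the 2 STAT effects had r = -0.134.

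Under the control inoculum, IL10-labelled samples had much higher signal of neutrophil, interferon-gamma and MHC class II genes than C57-labelled samples. The calprotectin subunits S100a8 and S100a9 were at least 82.4-fold and 54.1-fold higher, and Pla2g2a, a secreted antibacterial phospholipase, at least 29.8-fold. The bounds moved with single samples: S100a8 was at least 25.1-fold higher without IL10_control 2 and 269-fold without IL10_control 3, and S100a9 at least 18.2-fold and 166-fold. Cxcl9, induced by interferon-gamma, rose from 26.3 ± 9.37 SD to 1824 ± 258 SD (log2 6.10 ± 0.26, 68.8-fold, n = 3 and 3, adjusted p = 5.31e-08 in limma's test). Nox1, the epithelial NADPH oxidase, rose by 6.31 ± 0.36 (79.5-fold). Nos2 rose by 5.22 ± 0.34 (37.3-fold), and Il1b by 5.36 ± 0.87 (41.1-fold, with 26.6-fold without IL10_control 1 and 95.0-fold without IL10_control 3).

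Other large rises, given as lower bounds, were Cxcl10 (at least 15.7-fold), Clec4e, a lectin receptor of myeloid cells (7.33), Ctla4, a T cell inhibitory receptor (6.18), Cxcl1, a neutrophil chemokine (5.21), Il1a (4.03), Cxcl3 (3.28) and Marco, a macrophage scavenger receptor (2.73). Without IL10_control 3 the bounds were 12.4 for Clec4e, 9.25 for Cxcl1, 12.6 for Il1a and 10.2 for Cxcl3. Without IL10_control 2 they were 4.88 for Clec4e, 2.26 for Il1a, 1.76 for Cxcl3 and 1.61 for Marco, and without IL10_control 1 they were 2.29 for Il1a and 1.97 for Cxcl3. Of the genes always named, Tnf was at least 8.33-fold higher, Foxp3 at least 2.34-fold, Il10 at least 1.97-fold (adjusted p = 3.01e-06) and Il6 at least 1.49-fold. Il6 did not pass without IL10_control 2 (0.0535, where the mean lay under the floor) or WT_control 2 (0.0513), and was at least 3.13-fold higher without IL10_control 3. Il17a passed (2.72 ± 0.66, 0.00427, and 1.91 without WT_control 1), but its WT_control values were all under 20 and gave no bound above 1, and it stood at -0.50 under quantile normalization.

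The decreases were smaller. Cd109 changed by -1.70 ± 0.39, the chemokine scavenger Ccrl1 by -1.62 ± 0.23 and the TNF family cytokine Tnfsf15 by -1.37 ± 0.37. The cytokine Il15 changed by -1.23 ± 0.26, the IL-25 receptor Il17rb by -1.19 ± 0.28, the complement inhibitor C4bp by -1.09 ± 0.27, the chemokine Ccl6 by -1.01 ± 0.30 and the glycoprotein Cd24a by -1.01 ± 0.23. The complement gene C9 was at least 1.81-fold lower, and did not pass without IL10_control 2 (0.0572). The epithelial IL-17 receptor Il17re (-1.22 ± 0.36) did not pass without IL10_control 2 (0.0553) or WT_control 2 (0.0523). Btnl1, which maintains intraepithelial T cells (-0.84 ± 0.30), did not pass without IL10_control 2 (0.14), WT_control 1 (0.101) or WT_control 2 (0.116).

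Of the 457 genes 263 passed, 245 higher and 18 lower (93.2% higher), and that share followed the scaling. The panel median was 1.01, and relative to the median of each sample 337 passed, 154 higher and 183 lower (45.7% higher). Quantile normalization gave 310 (124 higher and 186 lower, 40%), and scaling on the 17 broadly expressed genes 300 (276 and 24). The same call held under every scaling for 112 higher and 18 lower genes, while 30 calls changed sign when centred. Without single samples the count ran from 235 to 264. The groups did not overlap for 280 genes (61.3%, where chance gives 10% on average).

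MHC class II rose in 8 of 8 members, with a median of 3.20 (camera adjusted p = 0.013, and adjusted p = 0.811 with an estimated correlation), including Cd74 (3.61 ± 0.23), H2-Ab1 (3.30 ± 0.21) and H2-DMa (3.58 ± 0.29). Th1 and interferon-gamma rose in 17 of 20 (median 2.27, 1.39 floored, 0.0342, and 0.811 with an estimated correlation), and had 0.113 with values under 20 set to 20, 0.0657 with the filter at 40, 0.0537 with array weights and 0.0742 on the broadly expressed genes (range 0.00768 to 0.113). The T cell list rose in 13 of 14 (2.12, 1.92 floored, 0.0401, and 0.811 with an estimated correlation), including Cd3d (2.12 ± 0.20), Cd4 (2.12 ± 0.28) and Cd6 (at least 3.58-fold). It lost its camera call without WT_control 1 (0.0637) and on the broadly expressed genes (0.0969, range 0.00836 to 0.0969). Macrophage and monocyte genes rose in 12 of 13 (2.02, 1.79 floored, 0.0464, and 0.811 with an estimated correlation), including C1qb (2.03 ± 0.20), the Fc receptor Fcgr1 (2.55 ± 0.27) and Emr1 (1.74 ± 0.20), with 1 lower over the list alone. That call was lost without IL10_control 3 (0.0553), WT_control 1 (0.0637) or WT_control 2 (0.0998), with the filter at 40 (0.0657), pseudocount 10 (0.0624) and array weights (0.0537), on the broadly expressed genes (0.107) and with values under 20 set to 20 (0.108), over 0.0185 to 0.108.

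The other lists did not pass camera at the deposited scaling. When centred, camera called the inflammatory (0.0142), neutrophil (0.00836), antimicrobial (0.0144) and cytotoxic and NK (0.0486) lists higher. With an estimated correlation and the deposited scaling each of them had adjusted p = 0.811. Inflammatory genes rose in 16 of 18 (17 over the list alone, median 3.23, camera adjusted p = 0.0663), among them Ccl8 (4.45 ± 0.35), Ccl5 (3.39 ± 0.31) and the monocyte chemokine Ccl2 (4.03 ± 0.46). Neutrophil genes rose in 9 of 9 (3.99, 2.31 floored, 0.0891), with the Fc receptor Fcgr4 at 4.55 ± 0.42, and cytotoxic and NK genes in 9 of 9 (0.0986), with Gzma, a granzyme, at 5.37 ± 0.50 (41.4-fold, and 64.2-fold without WT_control 1). Antimicrobial genes rose in 6 of 7 (0.116), type I interferon in 9 of 14 (0.397), MHC class I and immunoproteasome in 6 of 9 (7 over the list alone, 0.215) with Psmb9 at 2.74 ± 0.19 and the peptide transporter Tap1 at 3.53 ± 0.26. IL-10 signalling rose in 5 of 8 (0.73), inflammasome in 6 of 11 (0.802), TLR, NOD and NF-kB in 7 of 28 (6 over the list alone, 0.215, camera direction lower at 0.00836 when centred, and adjusted p = 0.936 with an estimated correlation and the deposited scaling), regulatory T cell in 9 of 14 (0.416) and dendritic cell in 8 of 10 (0.397). Th17 had 6 higher and 1 lower of 15 (0.416), Th2 7 and 2 of 11 (0.889) and complement 11 and 2 of 18 (0.576).

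B cell genes rose in 6 of 12 (0.913), plasma cell genes in 2 of 4 (0.837), endothelium and stroma in 4 of 10 (3 over the list alone, 0.821) and the Peyer patch list in 7 of 13 (0.657), with its chemokine Ccl19 at least 7.73-fold higher (11.7 without IL10_control 3). Epithelium had 1 higher and 2 lower of 4 (0.14); the higher one, the mucin Muc1, was at least 2.57-fold higher but at -0.02 under quantile normalization. Camera gave the direction lower, against a positive median, for the Th17, inflammasome, TLR, Th2 and endothelium lists. The medians of the type I interferon, Th17, TLR, Th2, plasma cell and endothelium lists turned below 0 under at least 1 other scaling. The epithelium median (-0.07) turned to 0.02 on the broadly expressed genes, while its mean was 0.23. Of lists too small for camera, autophagy had Irgm1, an interferon-induced GTPase, at 2.07 ± 0.20 (adjusted p = 9.81e-06) and Atg16l1 at 0.06 ± 0.28. Mast cell and eosinophil had the Fc receptor chain Fcer1g at 2.11 ± 0.28 (7.87e-05), with Kit (-1.22 ± 0.52, 0.0671) and Ccr3 (0.23 ± 0.51) not passing, and the housekeeping reference had B2m at 1.79 ± 0.17.

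Under the STAT inoculum, 14 of the 16 inflammatory list members that rose under control were again higher in IL10-labelled samples. S100a9 was at least 71.9-fold higher, S100a8 rose by 8.52 ± 1.58 on the log2 scale (n = 3 and 3, adjusted p = 0.00124 in limma's test) and Pla2g2a was at least 39.2-fold higher. The fold of S100a8, 367, rested on values under 20 in WT_STAT 2 and 3 and was 146 without WT_STAT 3, 560 without IL10_STAT 1 and 733 without WT_STAT 1. Nos2 rose by 5.71 ± 0.34 (52.4-fold), Il1b by 5.71 ± 0.87 (52.2-fold) and Nox1 by 5.57 ± 0.36 (47.6-fold). Cd163 fell from 189 ± 47.7 SD to 16.0 ± 9.41 SD (-3.62 ± 0.45, 12.3-fold lower, adjusted p = 0.000114). Its IL10_STAT mean lay under the floor of 20, and the fold was 9.03 without IL10_STAT 2 and 16.3 without IL10_STAT 1. Il18 changed by -1.41 ± 0.22, from 532 ± 137 to 196 ± 24.7.

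Further rises were Clec4e (at least 13.0-fold), Il1a (9.66), Cxcl3 (9.21), Cxcl1 (8.02), Trem1, an amplifying receptor of neutrophils (2.27), and Il10 (1.91, adjusted p = 2.55e-06). Without IL10_STAT 1 the bounds were 17.5 for Il1a and 16.5 for Cxcl3, and without IL10_STAT 2 they were 6.03 and 5.55. Tnf was at least 12-fold, Il6 at least 3.00-fold, Foxp3 at least 1.80-fold (quantile normalization 0.0522) and Il17a at least 1.54-fold higher (0.0566 with values under 20 set to 20). Among the decreases, Cfd changed by -3.55 ± 0.89, Cd109 by -2.88 ± 0.39, Ccrl1 by -2.48 ± 0.23, the efflux pump Abcb1a by -2.40 ± 0.57 and the stem cell factor receptor Kit by -2.24 ± 0.52 (0.00472). Cd36 changed by -2.17 ± 0.35, the adhesion gene Ncam1 by -1.94 ± 0.47, Il17re by -1.80 ± 0.36 and the transcription factor Hlx by -1.71 ± 0.27. Cd209g, a lectin receptor, was at least 1.25-fold lower and did not pass without IL10_STAT 2 (0.0681), WT_STAT 1 (0.0887) or WT_STAT 2 (0.0572), with a bound of 1.88 without WT_STAT 3. Ccl25, the small intestinal homing chemokine (-1.71 ± 0.57), did not pass without IL10_STAT 1 (0.0639), 2 (0.0703) or 3 (0.0607), or without WT_STAT 1 (0.0792) or 2 (0.0563).

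Of the 457 genes 236 passed, 183 higher and 53 lower (77.5% higher). The panel median was 0.50, and relative to the median of each sample 281 passed, 136 higher and 145 lower (48.4%). Quantile normalization gave 280 (121 higher and 159 lower, 43.2%), and the broadly expressed genes 281 (228 and 53). The same call held under every scaling for 114 higher and 50 lower genes, and 1 call changed sign when centred. Without single samples the count ran from 190 to 220. The groups did not overlap for 295 genes (64.6%, where chance gives 10% on average).

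Th1 and interferon-gamma had 15 higher and 1 lower of 20 (median 2.08, 1.12 floored) and inflammatory genes 14 higher of 18 (3.61, 2.61 floored, with 1 lower over the list alone), both at camera adjusted p = 0.0105, and at 0.757 with an estimated correlation. MHC class II rose in 6 of 8 (2.22), and neutrophil genes in 8 of 9 (9 over the list alone, 3.70, 1.91 floored), both at 0.0248, and at 0.757 with an estimated correlation. In the alternatives with the preset correlation, MHC class II ran from 0.00912 to 0.0658, lost with only the 2 groups. Neutrophil ran from 0.00773 to 0.0983 and was lost on the broadly expressed genes, with values under 20 set to 20 (0.0535) and without the 2 samples of lowest depth (0.0542). Examples were Cxcl9 (4.93 ± 0.26), Ccl5 (3.08 ± 0.31), Cd74 (2.48 ± 0.23) and Fcgr4 (3.41 ± 0.42). The following did not pass camera at the deposited scaling. T cell had 11 higher of 14, cytotoxic and NK 8 of 9 (9 over the list alone), antimicrobial 5 of 7 and MHC class I 6 of 9 (all 0.0696). Macrophage had 9 higher and 1 lower of 13 (10 higher over the list alone, 0.123). Type I interferon rose in 8 of 14 (0.135), IL-10 signalling in 4 of 8 (5 over the list alone, 0.498) and the Peyer patch list in 5 of 13 (0.795). Camera called the antimicrobial list higher when centred (0.0197), and the MHC class I list on the broadly expressed genes (0.0487). With an estimated correlation and the deposited scaling both had adjusted p = 0.757.

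The epithelium list had 0 higher and 2 lower of 4 (median -0.73, 0.0697), with Cd24a at -1.61 ± 0.23 and the cytokine Tslp at least 2.34-fold lower, and fry gave it 0.0148. Th17 had 5 higher and 2 lower of 15 (0.498), with a median of -0.01 against a mean of 0.87, and the median turned to 0.20 on the broadly expressed genes. Inflammasome had 6 and 1 of 11 (0.795), TLR 5 and 1 of 28 (0.552), Th2 7 and 2 of 11 (0.721), regulatory T cell 5 and 1 of 14 (0.721), complement 10 and 3 of 18 (0.721), dendritic cell 6 and 2 of 10 (0.609) and endothelium and stroma 2 and 2 of 10 (0.175). B cell genes had 0 of 12 past the threshold (0.598; 0 over the list alone), and plasma cell genes 1 of 4 (0.721), with a median of -0.02 against a mean of 0.17. The medians of the TLR, regulatory T cell and B cell lists, above 0 as deposited, turned below 0 under at least 1 other scaling, camera gave the TLR and B cell lists the direction lower, and the plasma cell median turned to 0.20 on the broadly expressed genes. Irgm1 rose by 2.05 ± 0.20, Fcer1g by 1.18 ± 0.28 (0.00526) and B2m by 1.48 ± 0.17, while Atg16l1 (-0.10 ± 0.28) and Ccr3 (-0.19 ± 0.51) did not pass.

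The 2 genotype contrasts shared 178 of their higher genes (98.1 for independent lists) and 18 lower genes (2.09 for independent lists), with 0 calls in opposite directions. These contrasts had no samples in common, but both came from 1 fit with shared variances. The same difference in counts above background between the genotype labels also entered both, and the numbers for independent lists take no account of this. The log2 differences of the 2 contrasts had r = 0.913 across genes. Genes are not independent replicates, so no p-value is given for that correlation. S100a8, S100a9, Pla2g2a, Nox1, Nos2, Il1b and Cxcl9 were among the genes higher under both inocula, and Cd109, Ccrl1 and Cd24a among those lower under both.

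**Figure D4:**
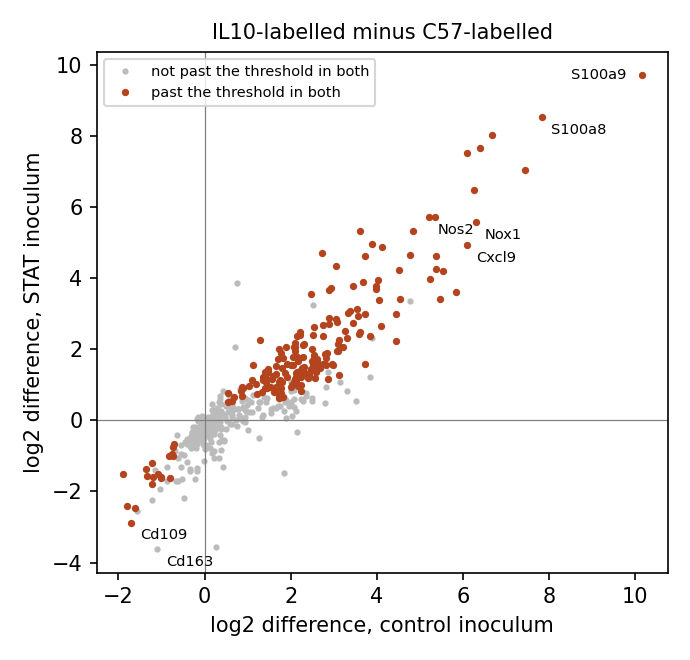
Log2 difference between IL10-labelled and C57-labelled samples under the control inoculum against that under the STAT inoculum, for the 457 tested genes. The values are as deposited, and relative to the median of each sample the share of higher calls dropped under both inocula.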

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

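The 9 tests below that do not regroup samples, and the list of 17 broadly expressed genes, were chosen only after the results were seen, while the counts over regrouped samples were planned before.

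Il10 was at or near 0 in the C57-labelled samples and above 20 in the IL10-labelled samples. With values under 20 set to 20, the log2 differences between genotype labels, minus the panel median differences with the same floor, were 0.118 ± 0.321 under control and 0.568 ± 0.321 under STAT. Both are lower bounds set by that floor, so they decided nothing and a panel-wide difference in level stayed open. On the first principal component computed without Il10, the number of samples on the side of the other genotype label was 0, which argued against an exchange of a few samples. An exchange of all genotype labels stayed open, because the values pointed both ways. The Il10 signal ran in the direction that an exchange would give. By contrast, 14 genes of the inflammatory list were higher in the IL10-labelled samples under both inocula. If IL10-deficient tissue was the more inflamed, the labels as given would yield that direction and an exchange the opposite. A transcript of the disrupted allele that the probe binds may give the same Il10 signal. This was not tested, since the probe position was not given in the sources used here.

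In the C57-labelled samples the mean difference of Irf4, Slamf7, Cxcl9 and Ccl8 with STAT was 1.51 ± 0.148, and that of the MHC class II list 1.03 ± 0.278. With the mean of the B cell list as a covariate, the 4 genes, chosen because they had passed, had 1.5 ± 0.184, but none of them passed any longer. Irf4 went from 1.72 ± 0.25 to 1.63 ± 0.28, Slamf7 from 1.11 ± 0.20 to 0.97 ± 0.22, Cxcl9 from 1.38 ± 0.26 to 1.56 ± 0.28 and Ccl8 from 1.83 ± 0.35 to 1.85 ± 0.41. Their adjusted p was 0.0553 for Irf4 and Cxcl9 and 0.115 for Slamf7 and Ccl8 (0.00111 to 0.509 over all alternatives of the 4 genes). The standard error of each grew, and the folds of Irf4 and Slamf7 shrank. The unadjusted p of Cxcl9 in limma's test barely moved, from 0.000233 to 0.000242. What ended each call was not tested. The mean fold left by the covariate cannot decide whether a greater share of B cells or follicles was the cause. The 4 genes were picked in this same comparison, and the slope of the covariate was shared with the IL10-labelled groups. Slamf7 alone, at 0.54 when reduced by 2 standard errors, missed the bound of 0.56 applied to it. MHC class II dropped to 0.646 ± 0.19, which left that cause open for it. With each sample centred on its median, the 4 genes had 1.14 ± 0.279 and MHC class II 0.659 ± 0.126, so sample scaling or depth may account for part of both. Of the 10 splits of the 6 samples, 1 gave as many passing genes (4, highest other 1) and 3 as many lists (3, highest other 5), and with 10 splits a share under 0.05 cannot be reached. Litter and mother were not given in the labels and stay open.

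The STAT effect differed between genotype labels by camera for MHC class II (lower in IL10-labelled samples, adjusted p = 0.00301), inflammatory cytokines and chemokines (higher, 0.0188) and macrophage and monocyte genes (lower, 0.0373), and each had 0.743 with an estimated correlation. Of 100 regroupings of the samples, 49 gave as many lists (3, highest other 7), so chance was not excluded for the number of lists. All 100 gave as many genes, since the real count was 0, and the highest other count was 18. The regrouping with 18 genes exchanged the inoculum labels of all IL10-labelled samples, and of WT_control 2 and 3 with WT_STAT 1 and 2. It placed WT_control 3 and WT_STAT 3, the 2 samples of lowest depth, in the same group. Such a count may point to a structure of the samples or arise by chance as the highest of many, and neither was tested.

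For STAT in IL10-labelled samples, all 10 splits of the 6 samples gave as many genes (0, highest other 0) and 7 as many lists (4, highest other 6), and a share under 0.05 cannot be reached with 10 splits.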

How the results depend on the processing

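The 4 alternatives added after the results were seen were the scaling on broadly expressed genes, values under 20 set to 20, leaving out the 2 samples of lowest depth, and the B cell mean as a covariate; the others were planned before. Scaling on housekeeping genes was not run, because the table held 1 gene of that list, and a count model was not run, because counts could not be recovered after background subtraction. No paired analysis was possible because the replicate numbers follow only the order of the records and the labels pair no samples. Values where both groups sit at the floor of 20 have no difference. Where a setting changed a result, the cause was not tested. Of the named values, 9 of 319 changed sign for STAT in IL10-labelled samples, 13 of 330 for STAT in C57-labelled samples, 22 of 413 for the interaction, 9 of 1735 for genotype under control and 0 of 1602 for genotype under STAT. Of the genes that passed, 0 of the 4 for STAT in C57-labelled samples passed in every alternative, against 69 of the 103 named for genotype under control and 80 of the 95 under STAT.

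The number of genes for STAT in IL10-labelled samples, 0, was 40 with array weights and 3 without the 2 samples of lowest depth. For STAT in C57-labelled samples, 4 became 0 with each sample centred on its median, 0 with quantile normalization, 0 with only the 2 groups compared and 0 with the B cell mean as a covariate. It was 7 with trended and robust variance, 83 with array weights and 31 without the 2 samples of lowest depth. Without single samples it ran from 0 to 44 (0 without WT_control 1 or WT_STAT 1, 2 without WT_STAT 2, 44 without WT_STAT 3). Scaled on broadly expressed genes it stayed 4, of which only 2 were among the 4 genes called before. For the interaction, 0 became 132 with array weights, 59 without the 2 samples of lowest depth, and from 0 to 58 without single samples (1 without WT_control 3 or WT_STAT 2, 58 without WT_STAT 3). The array weights ran from 0.121 for WT_control 3 to 4.36 for IL10_STAT 3, with a warning that they had not converged.

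The number of lists for STAT in IL10-labelled samples, 4, was 0 with the estimated correlation, 0 with fry in place of camera, and 2 to 4 without single samples (2 without IL10_control 2). For STAT in C57-labelled samples, 3 became 0 with the estimated correlation, 1 with quantile normalization, 1 with the filter at 40 in 6 samples, 1 with only the 2 groups compared, 5 with array weights, 1 when scaled on broadly expressed genes, and 1 to 4 without single samples (1 without WT_control 1 or 2). For the interaction, 3 became 0 with the estimated correlation, 0 with fry, 1 with no filter on low values, 5 with pseudocount 10, 1 with array weights, 5 with values under 20 set to 20, and 1 to 5 without single samples (1 without IL10_STAT 2, 5 without IL10_control 3 or WT_STAT 3). For genotype under control, 4 became 0 with the estimated correlation, 21 with fry, 9 with each sample centred on its median (8 higher and 1 lower, TLR, NOD and NF-kB), 8 with quantile normalization (7 higher and 1 lower), 2 with the filter at 40 in 6 samples, 2 with array weights, 1 when scaled on broadly expressed genes, 2 with values under 20 set to 20, and 2 to 5 without single samples (2 without WT_control 1, 5 without IL10_control 3). For genotype under STAT, 4 became 0 with the estimated correlation, 17 with fry and 7 with the filter at 40 in 6 samples.

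For STAT in IL10-labelled samples (STAT_in_IL10), Il10 was 0.24 with each sample centred on its median, 0.41 with quantile normalization, 0.15 with array weights, 0.074 when scaled on broadly expressed genes, and -0.38 to 0.39 without single samples. Without single samples Il1b ran from -0.19 to 1.65, Il6 from -0.061 to 1.66 and Nos2 from -0.15 to 0.29. The lowest values of Il1b and Il6, which differed by 1.02 and 1.01 with all samples, were those without IL10_control 3.

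For STAT in C57-labelled samples (STAT_in_C57), Il1b was -0.45 with the B cell mean as a covariate. Il6 was -0.25 with each sample centred on its median, -0.71 with the B cell mean as a covariate, and -0.85 to 1.09 without single samples. Nos2 was 0.065 without the 2 samples of lowest depth. Foxp3 was -0.093 with each sample centred on its median, -0.093 with quantile normalization, -0.19 with array weights, -0.49 with the B cell mean as a covariate, and -0.93 to 1.20 without single samples.

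For the interaction, Il10 was -0.042 with values under 20 set to 20. Tnf was 0.52 with each sample centred on its median, 0.70 with quantile normalization, 0.13 with pseudocount 10, 0.20 with array weights, 0.53 with values under 20 set to 20, 0.093 without the 2 samples of lowest depth, and -0.84 to 0.39 without single samples. Il1b ran from -0.86 to 0.97 without single samples. Il6 was -0.26 with array weights, -0.37 without the 2 samples of lowest depth, and -0.18 to 1.86 without single samples. Nos2 was -0.0071 without the 2 samples of lowest depth, and Foxp3 ran from -1.59 to 0.54 without single samples.

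For genotype under control (genotype_in_control), quantile normalization gave Il17a -0.50, Bcl3 -0.10, Tnfrsf13b -0.30, Btk -0.30, Batf3 -0.13, Muc1 -0.020 and Icam2 -0.49. With each sample centred on its median, Icam2 was -0.16 and Fn1 -0.42.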

Other observations

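As in the patterns above, the tests of level and depth given here, with the 17 broadly expressed genes, were chosen only after the results were seen, and the counts over splits were planned before.

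The IL10_control samples differed widely from each other in neutrophil and follicle genes. S100a8 was 1712, 18686 and 161 and S100a9 1208, 9999 and 120 in IL10_control 1, 2 and 3, and Il1b was 1357, 1277 and 106. The antimicrobial peptide gene Camp was 12.6, 709 and 9.03, and the neutrophil protease gene Ctsg, not tested, was 0.564, 223 and 1.81. The B cell gene Ms4a1 (480, 855 and 62.5) was also lowest in IL10_control 3. In this sample the mean log2 signal was 6.02 for the neutrophil list, against 8.07 and 9.47 in the other 2, and 5.83 for the Peyer patch list, against 7.62 and 8.08. MHC class II, by contrast, had a spread of 0.25 SD around 12.03 in the same 3 samples.

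Several cytokine genes of T cells were near or below the filter. Ifng was 9.59, 12.4 and 6.14 in IL10_control and 10.5, 33.2 and 27.9 in IL10_STAT, with 1.46 as its highest value in C57-labelled samples. Il22 was 0 in all C57-labelled samples and reached 9.76 in 1 IL10-labelled sample. Il17f was 14.1 ± 6.51 SD in IL10_control and 24 ± 2.48 SD in IL10_STAT, against 8.46 ± 5.91 and 1.35 ± 2.34 in the C57-labelled groups. Tbx21, the Th1 transcription factor, was 13.3 ± 11.7 SD in IL10_control and 0 in IL10_STAT, below the filter. Cfd, tested, varied widely within groups, at 1136 ± 908 SD in WT_control and 150 ± 69.9 SD in IL10_STAT.

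The higher panel median in IL10-labelled samples under control (1.01) was weighed against 2 technical causes. The 17 broadly expressed genes differed by -0.0898 ± 0.153 between the same groups, so they did not share the shift. That cannot exclude the scaling factor of the deposited values as a cause. What the factor was fitted to was not given, and genes like those it was fitted to would lie near 0 by construction. The 228 genes above the median of mean expression had a median difference of 0.407, against 1.89 for the 229 below it. Lower technical depth with background subtraction in C57-labelled samples may therefore account for part of the shift. A panel chosen for immune genes and inflamed tissue may give the same pattern, and this was not tested.

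For IL10-labelled against C57-labelled samples, 1 of the 10 splits gave as many genes under control (263, highest other 0) and 4 as many lists (4, highest other 7). Under STAT 1 split gave as many genes (236, highest other 0) and 3 as many lists (4, highest other 5). With 10 splits a share under 0.05 cannot be reached in either comparison.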
